A study of Mus musculus with 12 samples.

How the data were processed

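Total RNA was extracted from islets in 6 BKO and 6 Cre samples with TRIzol, and a VAHTS Universal kit and a NovaSeq sequencer gave paired-end reads, per the labels' protocols. Per the submitters' processing notes, HISAT2 2.0.5, HTSeq and the mm10 build were used. The HTSeq version, the annotation and the strand setting are not given in the sources used here.

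The deposited per-sample values are raw read counts per gene symbol, 24421 genes followed by the 5 summary lines of htseq-count. Those lines name no gene and were kept out of library sizes and tests. In BKO and Cre libraries they held, on average, 9.90% and 9.41% (no feature), 1.21% and 1.18% (ambiguous), 18.6% and 20.2% (low alignment quality), 2.43% and 2.47% (not aligned) and 5.08% and 5.02% (not unique) of all counted reads. Cre-1 had 27.3% in the low-quality line. The series-wide table deposited by the authors, although called raw counts, holds CPM over all lines including the summary ones, since each column sums to 1000000. All of its values (100%) were whole multiples of the value of 1 read within 0.001 reads, and the recovered reads equalled the per-sample counts for all 24420 genes it holds; 1 gene of the per-sample counts is absent from it. The count test on the recovered reads, added after the data were examined, called 0 genes.

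Gene totals averaged 1.11e+07 in BKO and 1.19e+07 in Cre (exact two-sided permutation p = 0.0152, Benjamini-Hochberg 0.136 over the library measures). The floor used for a gene is 3 reads, between 0.238 and 0.284 CPM per library, and the interval of the Il22ra1 ratio is an exact (Clopper-Pearson) 95% interval for counting error only. Replicate libraries differed beyond sampling noise (chi-square per degree of freedom between 5.07 and 30.2 over pairs), so each was counted once.

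The main test was edgeR 4.0.16 (R 4.3.3): filterByExpr on genotype (13583 genes kept), TMM normalisation, glmQLFit with robust shrinkage, glmQLFTest, and Benjamini-Hochberg adjustment over all genes at 0.05. CPM values in the text use TMM-scaled library sizes. Fold changes are BKO against Cre, with standard errors from the test. Unless another tool is named, genes past the test over all genes are those called by edgeR. The biological coefficient of variation was 11.7%, and the median log2 fold change of all genes 0.0078. Exact two-sided permutation tests of 6 against 6 libraries use all 924 splits, with 0.00216 as the smallest p they can give. Coordinates, lengths, GC content and overlaps come from the GENCODE annotation of GRCm38, which is mm10.

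Before the data were examined, 32 gene lists were fixed from textbook knowledge: β-cell identity and insulin secretion, exocytosis, other endocrine cells, acinar, duct, endothelial, stellate and mesenchymal cells, macrophages, lymphocytes, adipocytes, Schwann cells and neurons, red blood cells, IL-22 receptor and JAK-STAT signalling, Reg genes, the cytochrome b5 system, unfolded protein response, antioxidant defence, respiratory chain, mitochondrially encoded genes, ribosomal proteins, glycolysis, cholesterol, fatty acids, dedifferentiation, cell cycle, interferon, inflammation, apoptosis, immediate early genes, the clock, hypoxia and sex chromosomes. No member of the mitochondrially encoded list was among the gene symbols, so 31 were tested with camera (limma 3.58.1, preset correlation 0.01), with fry and an estimated correlation beside it. Some lists share members, such as Sox9 in duct and dedifferentiation genes.

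The rule for named genes, also fixed before, takes Il22ra1, Cyb5r3, Ins1, Ins2, Gcg and Sst, then genes past the threshold, and where fewer than 5 pass in a direction the 5 with the smallest p (mean log2 CPM of at least 1, no predicted gene models), and up to 4 members with the smallest p in each list. For lists with no call, the examples were limited to at most 2 with an unadjusted p under 0.05; that limit was chosen after the values and their stability had been seen. Some list members that the rule takes are not reported here.

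Alternatives fixed before were RLE and upper-quartile scaling, TMM without acinar genes, no count filter or at least 10 reads in all libraries, DESeq2 1.42.0, limma-voom with quality weights, no robust shrinkage, the replicate number as a block, the acinar score or 1 surrogate variable (sva 3.50.0) as a covariate, other thresholds, and each library left out. The endothelial score as a covariate was added after the data were examined. Because that score was itself higher in BKO, it can take up part of the genotype difference. Counts simulated from the real means and library sizes, with 50 genes changed at each of 4 fold sizes among 13583, were tested in the same way. Genes were drawn independently with edgeR's dispersions in a single run, so correlation between genes was left out. The share recovered by edgeR was 36% at 1.25-fold, 74% at 1.5-fold, 92% at 2-fold and 94% at 3-fold with 12 false calls, and that by DESeq2 was 42%, 74%, 92% and 94% with 30 false calls.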

Results

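Islets, the clusters of hormone-secreting cells of the pancreas, were profiled by bulk RNA sequencing in mice kept on a high-fat diet for 6 weeks. Of the 12 libraries, 6 came from mice whose β cells, the insulin-producing cells, lacked interleukin-22 receptor subunit alpha 1 (Il22ra1βKO, here BKO). The other 6 came from Ins2Cre control mice (here Cre). The design asks how loss of this receptor subunit in β cells alters the islet transcriptome on this diet. The series title names cytochrome b5 reductase 3. Reads assigned to genes ranged from 10356093 to 11902217 in the BKO libraries and from 11444273 to 12397139 in the Cre libraries. The labels do not say whether each library is a separate animal, so p-values measure the spread between these samples.

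Il22ra1, the targeted gene, was barely detected in whole islets of either genotype. It lies on chromosome 4 from 135728172 to 135752140 on the plus strand (mm10, ENSMUSG00000037157.8). Libraries held between 1 and 5 of its reads, and 10 of the 12 held 3 or fewer, the floor used here. The BKO libraries were at 0.197 ± 0.0908 CPM (SD, n = 6) and the Cre libraries at 0.223 ± 0.153 CPM (SD, n = 6; exact two-sided permutation p = 0.708). The summed reads, 13 in BKO and 16 in Cre, gave a BKO to Cre ratio of 0.875 with a 95% interval of 0.387 to 1.94 that covers counting error only (exact binomial p = 0.853). A difference was therefore not detectable at this depth, and a count over the whole gene does not show whether a single floxed exon was lost. The difference between the group means turned positive without Cre-1 (0.0128 CPM) and without Cre-3 (0.00715 CPM).

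No single gene passed the main test, that of edgeR, between genotypes. At a preset correlation between genes, lists of blood vessel, mesenchymal and duct markers were called higher in BKO islets and a β-cell list lower. These calls were lost with an estimated correlation (adjusted p = 0.359 for each of the first 3 and 0.402 for the β-cell list). Of 13583 genes tested with edgeR, 0 were higher and 0 lower in BKO at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 1815 genes, 1182 of them higher and 633 lower, where about 679 would be expected by chance. DESeq2 called 169 higher and 54 lower, and limma-voom called 0. With the replicate number as a block, which the labels do not say pairs samples, edgeR called 364 genes. Without BKO-4 edgeR called 135 genes higher and 127 lower, without Cre-5 it called 105 and 5, without BKO-3 it called 5 and 0, and without Cre-1 it called 1 and 5.

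The genes with the smallest p that were higher in BKO were led by Rnd3, an atypical small GTPase, with a log2 fold change of 0.72 ± 0.12 (SE). It was at 15.02 ± 2.85 against 9.11 ± 0.786 CPM (SD, n = 6 each). Egfl7, a factor secreted by endothelial cells, followed at 0.50 ± 0.091, with 47.0 ± 4.87 against 33.3 ± 4.76 CPM. Onecut2, a transcription factor of liver and pancreatic duct cells, had a log2 fold change of 1.43 ± 0.26, Cyyr1 of 0.85 ± 0.17 and Rhoc, a small GTPase, of 0.46 ± 0.091. Among the lower genes, Glp1r, the receptor for the incretin hormone GLP-1, was at 211 ± 17.3 CPM in BKO and 269 ± 27.4 CPM in Cre, a log2 fold change of -0.35 ± 0.071. Asic1, a proton-gated cation channel, was at -0.37 ± 0.075, Kcnd1, a voltage-gated potassium channel, at -0.46 ± 0.099, Fdps, an enzyme of the mevalonate pathway, at -0.24 ± 0.051, and Tmem8 at -0.24 ± 0.050. All 10 had an adjusted p of 0.121 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the smallest reached, which 33 genes shared. DESeq2 on the same counts gave all 10 an adjusted p under 0.05, from 0.000499 (Rnd3, Onecut2) to 0.0140 (Kcnd1). Limma-voom called no gene. In each of the 10 all 6 BKO libraries lay on the same side of the Cre mean. Egfl7 (chromosome 2, 26580014 to 26593120) overlaps Agpat2 and Mir126b on the opposite strand and Gm20532 and Mir126a on the same strand. Cyyr1 overlaps Gm2541 and Fdps overlaps Gm43738, both on the same strand. Since the strand setting of the counting is not given in the sources used here, reads of the overlapping parts cannot be assigned with certainty. Glp1r lies on chromosome 17 from 30901817 to 30940791 with no overlapping gene.

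**Figure D1:**
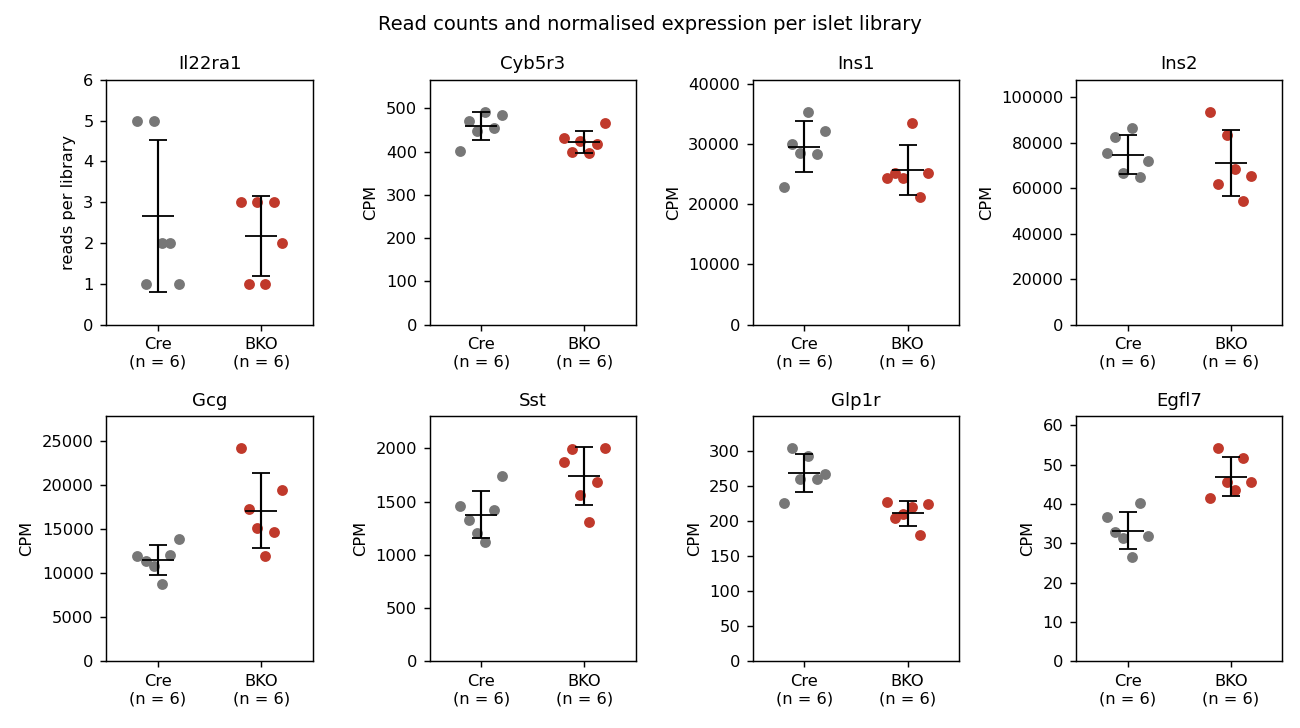
Reads of Il22ra1 per library, and CPM of Cyb5r3, Ins1, Ins2, Gcg, Sst, Glp1r and Egfl7, in 6 Cre (grey) and 6 BKO (red) islet libraries. Points are libraries, and bars are the mean with the SD. All 6 BKO libraries lie below the Cre mean for Glp1r and above it for Gcg and Egfl7. For Glp1r, Gcg and Egfl7 the adjusted p was 0.121, 0.159 and 0.121 by edgeR. By DESeq2 it was 0.00534, 0.0497 and 0.00389.

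Cyb5r3, the cytochrome b5 reductase of the series title, which passes electrons from NADH to cytochrome b5, was slightly lower in BKO without passing the test. It was at 423 ± 25.7 CPM in BKO and 459 ± 32.7 CPM in Cre (SD, n = 6 each), a log2 fold change of -0.12 ± 0.058 (SE) and a fold of 0.921, with 5 of 6 BKO libraries below the Cre mean (edgeR adjusted p = 0.391, exact two-sided permutation p = 0.0649). The gene lies on chromosome 15 from 83153494 to 83172592 on the minus strand and overlaps Gm49463 on the opposite strand. Of the 9 tested genes of the cytochrome b5 system, 8 had a negative fold change, with a median of -0.094. The list was called lower by camera (adjusted p = 0.0168; adjusted p = 0.359 with an estimated correlation). Its call was also lost with a surrogate variable (adjusted p = 0.706) and with the endothelial score as a covariate (adjusted p = 0.158). No member passed, either over all genes or adjusted over the list alone. Cyb5b, the outer mitochondrial membrane form of cytochrome b5, was at -0.13 ± 0.047, Cyb5r1 at -0.23 ± 0.12 and Cyb5d2 at -0.10 ± 0.11.

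The β-cell list was called lower, with small fold changes, and the list of the other islet endocrine cells higher, and both calls were lost with an estimated correlation. The median log2 fold change of 34 genes of β-cell identity and insulin secretion was -0.042, with 24 negative and 10 positive. The list was called lower (camera adjusted p = 0.000377; adjusted p = 0.402 with an estimated correlation). Over all genes 0 of the 34 passed, and adjusted over the list alone 6 fell. These were Glp1r, the transcription factors Pdx1 (-0.25 ± 0.061), Nkx6-1 (-0.20 ± 0.060) and Mafa (-0.35), the proinsulin convertase Pcsk1 (-0.31 ± 0.095) and pyruvate carboxylase Pcx (-0.16). Insulin itself did not pass, with Ins1 at -0.20 ± 0.11 (adjusted p = 0.440) and Ins2 at -0.071 ± 0.12 (adjusted p = 0.865). Both changed sign with a surrogate variable (0.085 and 0.13), as did Ins2 with the endothelial score (0.28). The near-identical sequences of these paralogs make the split of reads between them uncertain. The β-cell median was -0.12 without BKO-1, -0.070 without BKO-3, -0.078 without Cre-1, -0.077 without Cre-3, -0.087 with limma-voom and -0.026 with a surrogate variable, which ended the call (adjusted p = 0.365). With the endothelial score, itself higher in BKO, as a covariate the β-cell median was 0.037, and the list turned higher without passing (adjusted p = 0.687). Exocytosis genes had a median of -0.077 over 21 members and were called lower (camera adjusted p = 0.000837; adjusted p = 0.359 with an estimated correlation), with 0 members past the test over all genes or adjusted over the list alone. That call was lost with a surrogate variable (adjusted p = 0.706) and with the endothelial score (adjusted p = 0.463). Rab3a, a small GTPase of secretory vesicles, was at -0.24 ± 0.083 and Syt13 at -0.15 ± 0.057. Among 16 genes of the other endocrine cells the median was 0.33. The list was called higher (camera adjusted p = 7.52e-06; adjusted p = 0.381 with an estimated correlation, and 0.267 with a surrogate variable). Adjusted over the list alone 9 of the 16 rose, against 0 over all genes. They included glucagon, Gcg, at 17144 ± 4290 CPM in BKO and 11508 ± 1689 CPM in Cre (0.58 ± 0.15, adjusted p = 0.159 over all genes, exact two-sided permutation p = 0.00866), the α-cell transcription factor Irx2 (0.55 ± 0.16) and Ttr (0.61 ± 0.17). Somatostatin, Sst, was at 1738 ± 273 against 1379 ± 220 CPM (0.33 ± 0.12, adjusted p = 0.245 over all genes). Of the 16 genes 15 had a positive fold change. The exception was the hormone ghrelin, Ghrl (-0.42 ± 0.38), which like the hormones Pyy (0.25 ± 0.17) and Ppy (0.28 ± 0.22) did not pass either adjustment; these 3 were chosen after their values were seen. The endothelial, stellate and duct medians in these libraries were 0.42, 0.35 and 0.28.

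Endothelial markers were the cell-type group with the smallest camera p, while duct markers had the smallest exact permutation p of the score (0.00866, against 0.0108 for endothelial markers). Each of the 16 members was higher in BKO, with a median log2 fold change of 0.42. The list was called higher (camera adjusted p = 1.2e-11; adjusted p = 0.359 with an estimated correlation). With a surrogate variable the median was 0.19 and the list was still called (adjusted p = 0.000332). Over all genes 0 passed with edgeR, 8 with DESeq2 and 10 with the replicate number as a block, which the labels do not say pairs samples. Adjusted over the list alone 13 rose. Among them were Flt1, a VEGF receptor (0.52 ± 0.10), the junction protein Pecam1 (0.40 ± 0.081, 112 ± 11.8 against 84.4 ± 10.1 CPM) and Esam (0.49 ± 0.10). Stellate and mesenchymal markers had a median of 0.35 over 18 genes (camera adjusted p = 2.73e-06; adjusted p = 0.359 with an estimated correlation). Adjusted over the list alone 6 of them rose, including the pericyte marker Rgs5 (0.50 ± 0.10), Thy1 (1.21 ± 0.33) and the proteoglycan Lum (1.14 ± 0.33), and also Sparc (0.38 ± 0.12), against 0 over all genes. The stellate list turned lower without passing with a surrogate variable (adjusted p = 0.706) and with the endothelial score (adjusted p = 0.201). Duct markers had a median of 0.28 over 15 genes (camera adjusted p = 0.000773; adjusted p = 0.359 with an estimated correlation). Adjusted over the list alone 4 rose, Onecut2, Muc1 (0.82 ± 0.24), Sox9 (1.04 ± 0.32) and the keratin Krt19 (1.43 ± 0.46), against 0 over all genes. The duct call was lost with a surrogate variable (adjusted p = 0.932) and with the endothelial score (adjusted p = 0.582). Acinar markers, transcripts of the enzyme-secreting exocrine pancreas, had the highest median, 0.52 over 27 genes (camera adjusted p = 2.58e-05; adjusted p = 0.493 with an estimated correlation). They varied widely between libraries, with a mean log2 CPM of 5.75 ± 0.730 in BKO and 4.80 ± 1.42 in Cre (exact permutation p = 0.177). The acinar call was lost with a surrogate variable (adjusted p = 0.23) and with the endothelial score (adjusted p = 0.631). No member passed over all genes or adjusted over the list alone. Macrophage and antigen presentation genes went the other way, with a median of -0.097 over 20 genes (camera adjusted p = 0.0434; adjusted p = 0.566 with an estimated correlation). Their members moved apart: adjusted over the list alone the dendritic cell integrin Itgax fell (-1.24 ± 0.28) and the lipopolysaccharide co-receptor Cd14 rose (1.27 ± 0.32), with 0 past the test over all genes. That list was no longer called without BKO-1 (adjusted p = 0.147), BKO-4 (0.137), BKO-6 (0.347), Cre-1 (0.0534), Cre-2 (0.127), Cre-3 (0.0632) or Cre-4 (0.405), nor with RLE size factors (0.071), the strict count minimum (0.173), DESeq2 (0.104) or a surrogate variable (0.267).

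**Figure D2:**
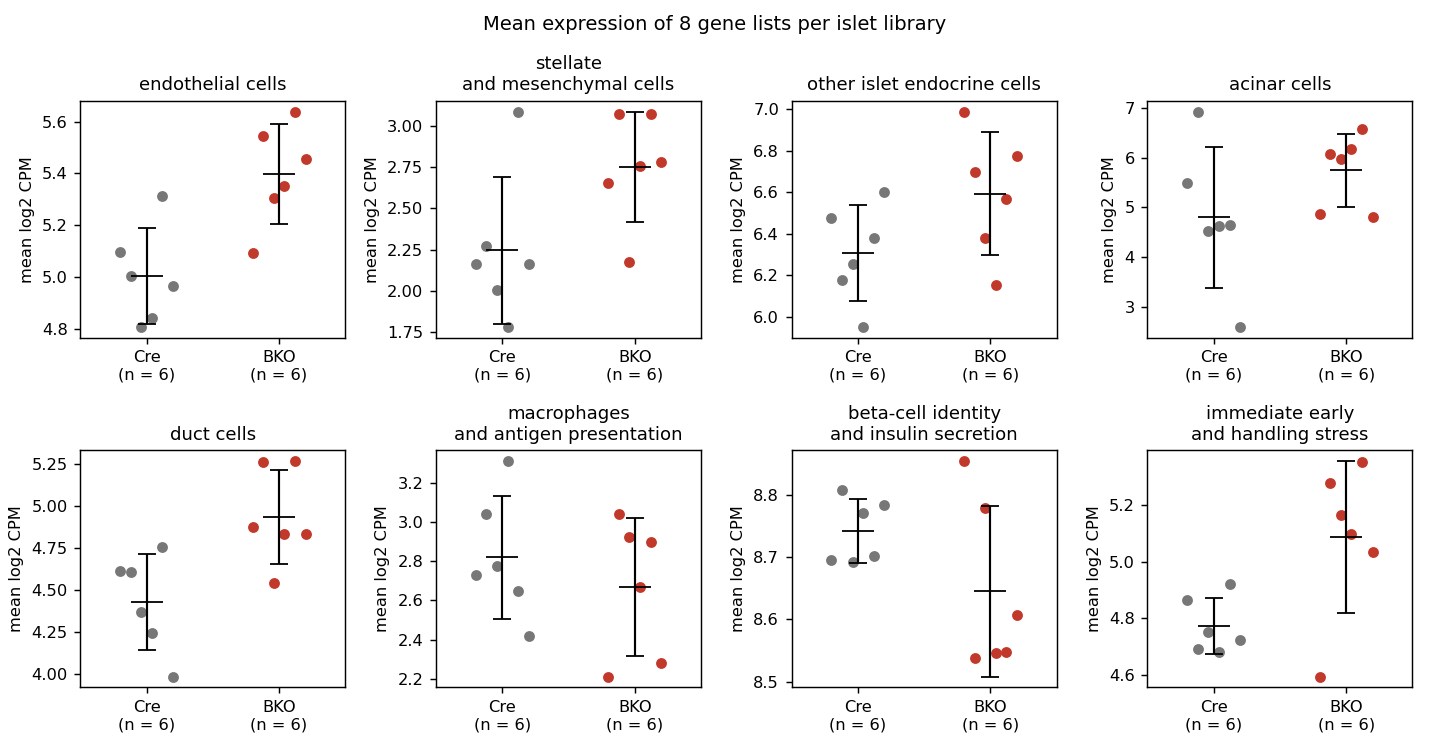
Mean log2 CPM of 8 gene lists in each of 6 Cre (grey) and 6 BKO (red) islet libraries, with the group mean and SD. Endothelial and duct scores lie higher in BKO (5.40 against 5.004, and 4.94 against 4.43), while the macrophage score does not (2.67 against 2.82). After adjustment over the lists no score passed an exact permutation test, which a single list on its own could not have passed.

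Lists of inflammation and of early stress responses were called higher in BKO, but each of these calls was lost with the endothelial score, a surrogate variable or both. The endothelial score was itself higher in BKO (5.40 against 5.004, exact permutation p = 0.0108). Like the surrogate variable, it can take up part of the genotype difference, so a lost call does not give its cause. Inflammatory mediators had a median of 0.37 over 23 genes (camera adjusted p = 8.22e-07; adjusted p = 0.359 with an estimated correlation). Although 13 members were higher at an unadjusted p under 0.05, none passed over all genes or adjusted over the list alone. The cytokine Il6 was at 27.1 ± 16.5 against 9.32 ± 4.82 CPM (1.53 ± 0.47), the chemokine Cxcl5 at 1.58 ± 0.49, Cxcl2 at 1.00 ± 0.32 and the NF-κB inhibitor Tnfaip3 at 0.50 ± 0.16. The inflammatory call was lost with the endothelial score (adjusted p = 0.582), and the list turned lower without passing with a surrogate variable (adjusted p = 0.23). Immediate early and handling stress genes, which respond within minutes to stimulation or tissue handling, had a median of 0.31 over 24 genes (camera adjusted p = 1.25e-06; adjusted p = 0.359 with an estimated correlation). Of these, Ier2 (0.42 ± 0.10), Egr1 (0.50 ± 0.15), Jun (0.36 ± 0.11) and Ier3 (0.61 ± 0.19) rose adjusted over the list alone, against 0 over all genes. The immediate early call was lost with the endothelial score (adjusted p = 0.974) but held with a surrogate variable (camera adjusted p = 0.0145). Hypoxia response genes had a median of 0.29 over 18 members (camera adjusted p = 8.02e-05; adjusted p = 0.402 with an estimated correlation). Of these, Higd1a (0.79 ± 0.19), the oxygen-regulated transcription factor Hif1a (0.29 ± 0.077) and the prolyl hydroxylase Egln3 (1.66 ± 0.51) rose adjusted over the list alone, with 0 over all genes. The hypoxia call was lost with a surrogate variable (adjusted p = 0.15). Dedifferentiation and disallowed genes, which mature β cells normally repress, had a median of 0.35 over 24 genes (camera adjusted p = 0.000136; adjusted p = 0.359 with an estimated correlation). Acot7 (0.84 ± 0.18), Cxcl12 (0.59 ± 0.17) and Sox9 rose adjusted over the list alone, with 0 over all genes. Sox9 is also a duct marker and Cxcl12 is also made by mesenchymal cells, and the endothelial, stellate and duct medians in these libraries were 0.42, 0.35 and 0.28. The dedifferentiation list turned lower without passing with a surrogate variable (adjusted p = 0.793), and its call was lost with the endothelial score (adjusted p = 0.974). Apoptosis genes had a median of 0.092 over 20 genes (camera adjusted p = 0.00899; adjusted p = 0.359 with an estimated correlation), with no member past the test over all genes or adjusted over the list alone. The apoptosis call was lost with the acinar score (adjusted p = 0.0876), a surrogate variable (0.985) and the endothelial score (0.974).

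Genes of the IL-22 receptor and JAK-STAT pathway did not move as a group, but single members went both ways. The list of 18 tested genes was not called (camera adjusted p = 0.243, median 0.034). Adjusted over the list alone 7 rose, the acute-phase gene Lbp (1.42 ± 0.33), Pim1 (0.35 ± 0.12), Jak2, Lcn2, Bcl3, Il10rb and Socs3. In the same adjustment 2 fell, Cish (-0.37 ± 0.10) and Socs2, which encode feedback inhibitors of cytokine signalling. Over all genes 0 passed. The 5 tested Reg family genes were not called (adjusted p = 0.341, median 0.13), nor were interferon response genes (26 tested, adjusted p = 0.131, median 0.15). Neither list had a member past the test over all genes or adjusted over the list alone. Interferon genes were called higher without BKO-3 (adjusted p = 0.0242), BKO-6 (0.00141), Cre-1 (0.000322), Cre-3 (0.0299) or Cre-4 (0.0409), and Reg genes without Cre-2 (0.0223). In the opposite direction, interferon genes were called lower with a surrogate variable as a covariate (adjusted p = 0.000895) and Reg genes with the acinar score (0.000622).

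Lists of the unfolded protein response and of sterol synthesis were called lower and that of cytosolic ribosomal proteins higher, and all 3 calls were lost with an estimated correlation. Genes of the unfolded protein response had a median of -0.094 over 32 members (camera adjusted p = 8.02e-05; adjusted p = 0.402 with an estimated correlation), with none past the test over all genes or adjusted over the list alone. Creld2 was at -0.24 ± 0.075 and Sel1l, of the degradation machinery of the endoplasmic reticulum, at -0.26 ± 0.088. The list turned higher without passing with a surrogate variable (adjusted p = 0.888). Cholesterol synthesis genes had a median of -0.073 over 24 genes (camera adjusted p = 0.00439; adjusted p = 0.359 with an estimated correlation). Fdps fell adjusted over the list alone, the 1 member to do so, against 0 over all genes. The cholesterol call held with a surrogate variable (camera adjusted p = 0.000332). Of 76 cytosolic ribosomal protein genes 74 were higher, with a median of 0.11 (camera adjusted p = 1.6e-11; adjusted p = 0.402 with an estimated correlation). Of these 19 reached an unadjusted p under 0.05 and none passed over all genes or adjusted over the list alone. Rpl32 was at 0.19 ± 0.063. The ribosomal call was lost with a surrogate variable (median 0.0092, adjusted p = 0.706). Glycolysis was not called (20 tested, adjusted p = 0.0616, median 0.19). It was called higher without BKO-3 (adjusted p = 0.015), BKO-6 (0.000717), Cre-3 (0.0464), Cre-4 (0.0063) or Cre-6 (0.0172), and with no count filter (0.0377), the strict count minimum (0.0418), DESeq2 (0.0175) or the endothelial score (0.0413). Fatty acid synthesis and oxidation was not called (27 tested, adjusted p = 0.712), with a test direction of lower beside a median of 0.022. Ehhadh, an enzyme of peroxisomal fatty acid oxidation, fell adjusted over the list alone (-0.39 ± 0.099), with 0 over all genes. The nuclear-encoded respiratory chain was not called (87 tested, adjusted p = 0.431), with a median of 0.0023 beside a test direction of lower and no member past either adjustment. It was called lower without BKO-1 (adjusted p = 0.0162), BKO-3 (0.0242) or Cre-3 (0.0364), and higher with the endothelial score (0.0413).

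Of the remaining lists, none was called and none had a member past the test over all genes or adjusted over the list alone. Antioxidant defence had a median of 0.040 over 36 genes (adjusted p = 0.182), the circadian clock of 0.057 over 17 (adjusted p = 0.241) and the cell cycle of 0.025 over 25 (adjusted p = 0.315). Lymphocyte markers, of which 2 could be tested, had a median of 0.28 (adjusted p = 0.157) and were called higher without Cre-5 (adjusted p = 0.0283). Markers of adipocytes (3 tested, median 0.11, adjusted p = 0.465), Schwann cells and neurons (7, 0.068, 0.923) and red blood cells (2, 0.12, 0.458) did not pass. Of the sex chromosome genes the 4 tested, all Y-linked, had a median of 0.036 (adjusted p = 0.712) and were called higher with the endothelial score (adjusted p = 0.0426).

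**Figure D3:**
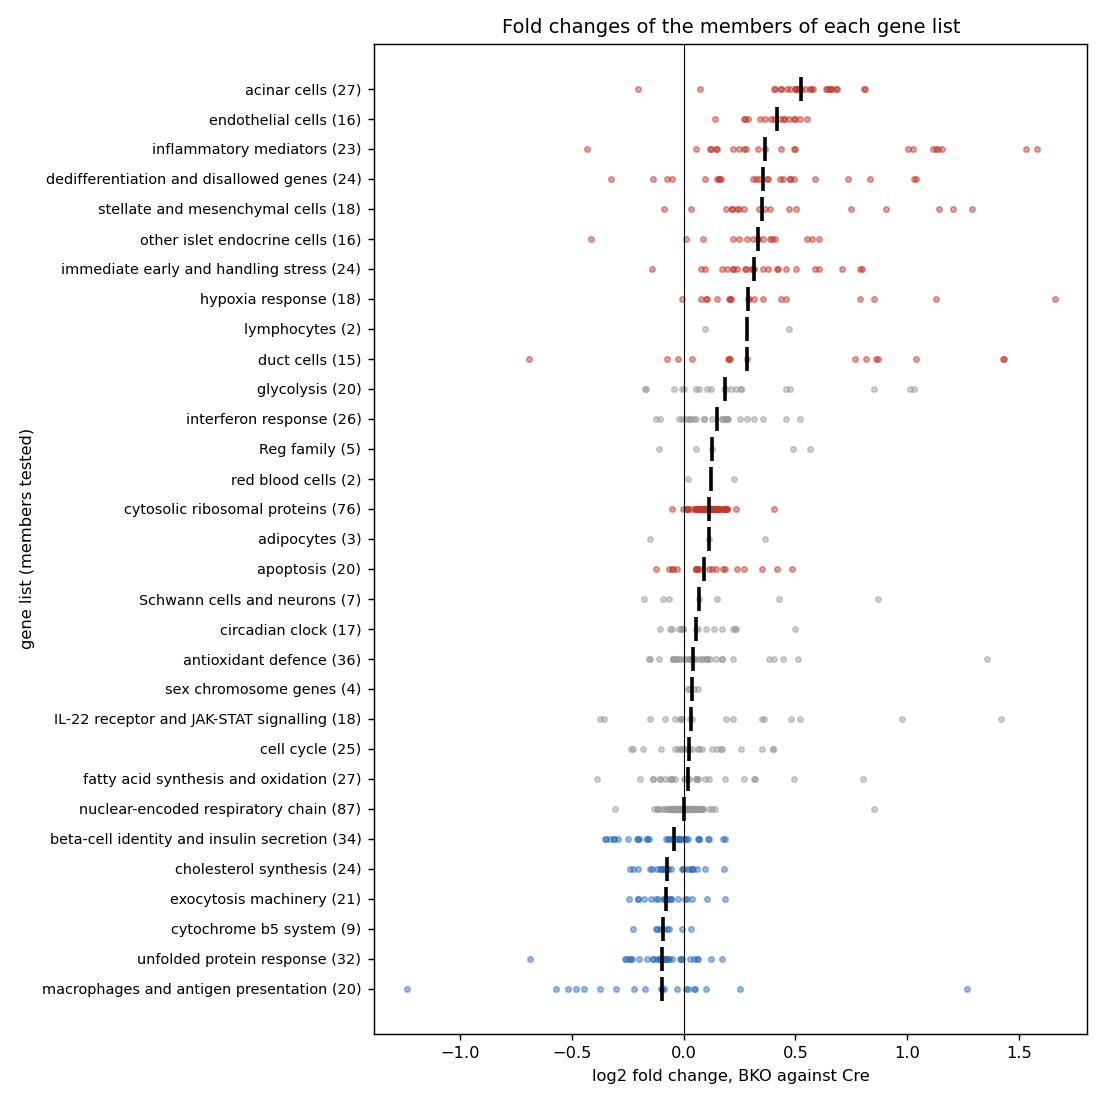
Log2 fold changes of the members of 31 gene lists, BKO against Cre islets, each point a gene and each black bar the list median. Lists called higher (red, 11) or lower (blue, 6) by camera at a preset correlation are coloured, the others are grey; with an estimated correlation 0 lists passed.

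In all, camera called 17 of 31 lists, 11 higher and 6 lower, whereas 0 passed with an estimated correlation, 0 by fry and 0 by exact permutation of the per-library scores after adjustment. The exact permutation p cannot fall under 0.00216, so after adjustment over 31 lists no single list on its own could pass. With 1 surrogate variable as a covariate 3 of the 17 were still called in the same direction. These were the endothelial, cholesterol synthesis and immediate early lists. With the endothelial score 6 of the 17 were still called in the same direction. The endothelial list was among those lost with the endothelial score (median 0.0055), which was fixed in advance because its own score was the covariate. Among the called lists, stellate, dedifferentiation, inflammatory and unfolded protein response genes turned direction with the surrogate variable, and β-cell and stellate genes with the endothelial score. Besides the insulin genes, the fold changes of Muc1, Sox9, Egln3, Lcn2, Bcl3, Socs3 and Cxcl2 changed sign with the surrogate variable, and with the endothelial score that of Pim1 and Sparc did.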

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

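The tests with the macrophage score and with the acinar or endothelial score as a covariate were chosen after the results were seen; the split counts and the length and GC tests were fixed before. In 6 of 110 groups of 6 libraries 1 library stood apart from the others by its gap to the nearest, where about 5.5 would be expected by chance. These were the share of ambiguous reads in BKO-2 (1.27%), the share of reads with no unique alignment in Cre-1 (5.61%), Ins1 in BKO-4 (33547 CPM, the next library at 25185), Cyyr1 in BKO-3 (4.48 CPM), the lymphocyte score in BKO-4 (0.356) and the dedifferentiation score in Cre-5 (2.98).

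The endothelial list was called higher and the β-cell list lower in BKO islets at a preset correlation. Both calls were lost with an estimated correlation (camera adjusted p = 0.359 and 0.402). A lower share of β cells alone would raise the markers of every other cell type alike. The macrophage score minus the endothelial score differed between the groups, -2.73 ± 0.282 in BKO against -2.18 ± 0.422 in Cre (exact permutation p = 0.0260). That test cannot decide, because the macrophage list was picked after the results were seen and its own score did not differ (exact permutation p = 0.455). Medians of the other endocrine, stellate, duct and acinar lists were 0.33, 0.35, 0.28 and 0.52, against 0.42 for the endothelial list. A lower share of β cells therefore stays open. Acinar carry-over as the whole cause is argued against. With the acinar score as a covariate the endothelial median was 0.39 (camera adjusted p = 5.37e-10), against 0.42 without that covariate. A surrogate variable lowered the endothelial median to 0.19 (camera adjusted p = 0.000332). Of 100 splits of the libraries, 3 gave an endothelial p as small, the real one included (3.88e-13, smallest other 1.77e-15). That share lies under 0.05 for this list taken alone. It does not exclude chance, since not all possible splits were drawn and 31 lists were looked at. The endothelial call was also lost at an estimated correlation (adjusted p = 0.359). A change in vessel content, with the genotype or with islet isolation, stays open and untested.

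The ribosomal protein list was called higher in BKO at a preset correlation, with no member past the test and an exact permutation p of 0.0628 for its score. Of 10000 random lists matched on expression and length, 0% had a median as high as 0.11 (matched median -0.0085), and 0% of those matched on expression and GC content did (-0.031), which argues against both biases. With the endothelial score as a covariate the median was 0.090, against 0.11 without it, and the list was still called at the preset correlation (camera adjusted p = 0.000323). That call cannot decide on endothelial content, because at an estimated correlation the list was not called even without the covariate. With a surrogate variable, which can take up part of the genotype difference, the median was 0.0092 and the call was lost (adjusted p = 0.706), as it was at an estimated correlation (adjusted p = 0.402), so a wider trend across the libraries stays open. Chance could not be excluded, as 9 of 100 splits gave a p as small (real 1.04e-12, smallest other 4.57e-24).

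Of the 462 possible splits 100 were drawn. Because the real split gave 0 genes past the threshold, all 100 splits gave at least as many (highest other 66), and that count cannot test chance. The split with 66 genes set 5 BKO libraries and Cre-2 against the rest. The 1815 genes at an unadjusted p under 0.05 were matched or exceeded in 3 of 100 splits, the real one included (highest other 2563, from a split that mixed the genotypes). That share lies under 0.05, but with 100 of 462 splits drawn it makes chance less likely for that count without excluding it. The 17 called lists were matched or exceeded in 5 of 100 splits (highest other 19), so chance could not be excluded for them.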

How the results depend on the processing

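The endothelial covariate and the reads recovered from the series table were chosen after the data were examined; the other alternatives were fixed before. The count of 0 genes in each direction held under every other scaling, filter, threshold, covariate and limma-voom, and moved with DESeq2 (169 higher, 54 lower) and with the replicate block (292 higher, 72 lower). All 223 genes called by DESeq2 had the same direction in edgeR, which is no separate support because both used the same counts. Of the 223 genes 8 were in the endothelial list. On simulated counts DESeq2 made more false calls (30 against 12). That single run drew genes independently with edgeR's dispersions, so it cannot show whether the DESeq2 calls are false. Leaving out 1 library gave between 0 and 135 genes higher and between 0 and 127 lower, with 135 and 127 without BKO-4, 105 and 5 without Cre-5, 5 and 0 without BKO-3, and 1 and 5 without Cre-1. The cause was not tested. Same-numbered libraries deviated together in part (4 of 6 correlations over 0.1, between -0.072 and 0.26, and 7 of 12 libraries closest to their own number). The labels do not say that the numbers pair samples, and not every pair was over 0.1, so the numbers were not taken as pairs. Pairing of some of these libraries stays open, and the count of 0 depends on that choice. Cyb5r3 was lower under each alternative and did not pass in any. The mean difference for Il22ra1 ranged from -0.0555 to 0.0128 CPM over left-out libraries, and was above 0 without Cre-1 (0.0128) and without Cre-3 (0.00715).

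With a surrogate variable, which can take up part of the genotype difference itself, these log2 fold changes changed sign: Ins1 0.085, Ins2 0.13, Muc1 -0.057, Sox9 -0.049, Prph -0.21, Lcn2 -0.023, Bcl3 -0.022, Socs3 -0.028, Rpsa -0.0093, Hk2 -0.027, Hk1 -0.013, Smad3 -0.0054, Mcm3 -0.029, Cxcl2 -0.059, Egln3 -0.014, Pfkfb3 -0.039. With the endothelial score, which can also take up part of that difference, they were Ins2 0.28, Spink1 -0.0039, Amy2b -0.17, Sparc -0.061, Fabp4 -0.021, Pim1 -0.017, Mcm3 -0.23. Lists whose direction turned had these adjusted p with a surrogate variable: stellate cells 0.706, lymphocytes 0.932, adipocytes 0.932, Schwann cells 0.23, IL-22 receptor and JAK-STAT 0.706, Reg family 0.706, unfolded protein response 0.888, respiratory chain 0.638, dedifferentiation 0.793, cell cycle 0.793, interferon response 0.000895, inflammatory mediators 0.23. With the endothelial score they were β-cell identity 0.687, stellate cells 0.201, adipocytes 0.687, Schwann cells 0.631, IL-22 receptor and JAK-STAT 0.582, Reg family 0.582, respiratory chain 0.0413, cell cycle 0.687, and with the acinar score Reg family 0.000622, fatty acids 0.711, interferon response 0.691, sex chromosomes 0.979. Turned lists under other filters were adipocytes 0.732 with no low-count filter, Schwann cells 0.424 with at least 10 counts in all libraries. With a library left out they were Schwann cells (range 0.417 to 0.969) 0.927 without BKO-1, 0.817 without BKO-6, 0.904 without Cre-4, fatty acids (range 0.403 to 0.958) 0.92 without Cre-5, 0.958 without Cre-6, respiratory chain (range 0.0162 to 0.803) 0.803 without BKO-2, sex chromosomes (range 0.327 to 0.939) 0.671 without BKO-1, 0.939 without BKO-3, 0.885 without Cre-6. The cause was not tested. Depth limits Il22ra1 and other genes near 3 reads, and on simulated counts edgeR recovered 74% of 1.5-fold changes, so small changes in single genes can be missed.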

Other observations

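The tests of the β-cell score and of the other β-cell genes were chosen after the results they bear on were seen, and the test of the 9 genes was fixed before their values were seen. It came after Cish, Socs2, Prlr and Ehhadh, known to respond to or receive prolactin-like STAT5 signals in islets, had been picked from these data as lower in BKO (log2 fold changes of -0.37, -0.36, -0.31 and -0.39, none past the edgeR test over all genes).

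A candidate explanation is lower prolactin- or growth hormone-like signalling in BKO islets, a hypothesis whose own cause was not tested. For 9 further genes recalled as responsive to it (Tph1, Tph2, Ivd, Wipi1, Tnfrsf11b, Gbp8, Matn2, Cldn8 and Fkbp11), the mean log2 CPM was 5.72 ± 0.434 in BKO and 6.20 ± 0.198 in Cre (SD, n = 6 each; exact permutation p = 0.0433), with 9 of 9 genes and 5 of 6 BKO libraries lower and none of the genes past the edgeR test. The result is fragile, since the exact permutation p was under 0.05 in only 3 of 12 cases with a library left out: it was 0.0693 without BKO-1, 0.0541 without BKO-2, 0.0519 without BKO-3, 0.0671 without BKO-5, 0.0541 without Cre-1, 0.0714 without Cre-3, 0.0736 without Cre-4, 0.0584 without Cre-5 and 0.0671 without Cre-6. A lower share of β cells would lower other β-cell genes about as much as the 4 picked genes. The median of 33 others was -0.034 (SD over genes 0.15) against -0.36. This cannot decide the question, because the 4 genes were picked as lower in these same data. For the 9 further genes a lower share of β cells cannot be told apart either. Their score minus the β-cell score, with a difference of -0.38, did not pass (exact permutation p = 0.128).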
